A study of Rattus norvegicus with 54 samples.

How the data were processed

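Gene expression was measured in gastrocnemius muscle of male Sprague Dawley rats with Affymetrix rat expression arrays, 1 array per animal, at 6 ages. The groups held 10 arrays at 6 months, 10 at 12 months, 10 at 18 months, 8 at 21 months, 9 at 24 months and 7 at 27 months, 54 in all. Per the labels, muscle was pulverized under liquid nitrogen, total RNA was purified with a column kit for fibrous tissue, and biotin-labelled cRNA was hybridised. The series' design text states that the rats were bought when 5, 11, 17 or 20 months old, without tying a purchase age to an animal. Scan dates, litters and array batches are not given in the sources used here, so no batch could be tested. Replicate numbers differ between ages and tie no animals together. The p-values of single genes below set differences between ages against the spread between the animals that the labels list. The number of arrays limits the precision.

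The deposited table holds 1 value per probe set and array on a log2 scale. Per the submitters' processing notes the authors summarised the probes with PLIER, a model that estimates 1 signal per probe set from its probes; its version, background step, offset and normalization are not given in the sources used here. The lowest deposited log2 value was 4.00 on every array, so values near it lie at a floor, and the fold change of a gene whose level in either group is close to that floor is bounded by it. The scale was read from the values, which run from this floor upwards as log2 values do.

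Of 31099 probe sets, 20826 carried 1 gene symbol in the platform's probe annotation, 436 carried several, 57 were controls and 9780 were unnamed here. Symbols were used as that annotation gives them. No gene positions are printed, because no genome build is tied to the array table. Each gene was represented by its probe set with the highest mean over all arrays, which gave 14217 genes. Genes were kept when at least 7 arrays, the size of the smallest group, lay above their own array's 40th percentile of all probe sets. This left 11244 genes for testing and removed 2973 dim ones. Where probe sets of a named list member, or of a gene named by the rule below, moved in opposite directions between 27 and 6 months, the text says so. Probe sets of the other single genes were not compared.

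The design set before the data were examined called for the values as deposited if array medians lay within 0.1 log2 of each other, and for quantile normalization otherwise. The medians ranged from 5.92 to 6.10, so quantile normalized values became the main setting. The planned pseudocounts were not used, because the deposited values already were logarithms. Quantile normalization gives all arrays the same distribution, so a change shared by most genes cannot be seen in these values. No scaling moved the median log2 change of all genes by more than 0.083 in any comparison between ages.

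All tests used limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) with 1 mean per age over all 54 arrays, so that the spread between animals was estimated from every age. Contrasts compared each later age with 6 months, each age from 18 months onward with the age before it, and the change from 18 to 27 months with the change from 6 to 18 months. A separate fit gave each gene 1 slope on age in months. All tests were two-sided. A gene is said to have risen, fallen or changed when its Benjamini-Hochberg adjusted p over the 11244 genes was under 0.05. Errors after log2 changes are standard errors from the fit, and errors after means are standard deviations. Comparisons with 6 months share the 6-month arrays, so their results are not independent of each other.

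In total 38 gene lists, covering muscle fibre types, nerve supply, energy metabolism, protein turnover, matrix, immune functions, stress pathways and the other cell types of muscle, were fixed before the data were examined. Each list was tested with limma's camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Of 681 list symbols on the array, 2 stand in more than 1 list, Cdkn1a and Gadd45a. A rule fixed at the same time chose genes to name in the text. It took the 10 largest rises and 10 largest falls among called genes between 27 and 6 months, the 3 largest of each for every other contrast, up to 4 list members with the smallest p between 27 and 6 months, and 16 genes always given. Symbols starting with LOC or RGD were left out. Some members that went against their list, and examples of list members at other ages and steps, were named after their values were seen. Values of single genes outside the rule were not recomputed under the alternatives.

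The spread between animals was each array's root mean squared distance over all tested genes from the mean of the other arrays of its age, scaled for group size, and compared with 6 months by an exact permutation test or, for ages with 10 animals, by 100000 permutations. List scores were the mean over members of the log2 value divided by the gene's standard deviation within ages. Their correlation was taken after subtracting each age's mean, with 100000 permutations within ages.

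The gene and list tests were run on simulated data made from the real residuals, shuffled across ages, with 200 genes changed by known amounts. There were 20 repeats of the comparison of 27 with 6 months over 11244 genes. The shuffle gives every age the pooled spread, so a wider spread at 27 months is not covered. The real comparison called 7751 genes, far more than were changed here. The test recovered 59.8% of genes changed by 0.25 log2, 95.0% of those changed by 0.5 and 99.2% of those changed by 1. With no gene changed, a median of 0 genes was called and the highest was 7. In the same unchanged data camera with the preset correlation called a median of 9 lists, and 15 at the highest, while camera with an estimated correlation called 0. Statements on gene groups therefore give the number of members called. Members of a list can move together, so such a count describes the list and is no test of it.

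The alternatives tried were the values as deposited, centring each array on its median, other variance models, other filters on dim genes, the mean of a gene's probe sets, every probe set by itself, only the arrays of the ages compared, and leaving out each 27-month animal or the whole 27-month group. For the spread and the correlations they were another distance, another score and leaving out the 2 most extreme arrays. Alternatives chosen after seeing the data added the difference between the 3' and 5' probe sets of beta-actin, of hexokinase or of GAPDH, measures of RNA quality, as a covariate. Figures were drawn with matplotlib 3.10.9.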

Results

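RNA from the gastrocnemius, the large calf muscle, was profiled on 1 expression array per male Sprague Dawley rat at 6 ages. There were 10 rats at 6 months, 10 at 12 months, 10 at 18 months, 8 at 21 months, 9 at 24 months and 7 at 27 months. The title of the series names mitochondrial function and the nerve-muscle junction in the loss of muscle with age, and the comparisons ask which transcripts differ between ages and when. Array medians of the deposited log2 values lay between 5.92 and 6.10, and the number of arrays limits the precision. Of the 14217 genes with a named probe set, 11244 were bright enough to test. Changes below are on the log2 scale with their standard error, unless a fold is named.

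The 3 measures of RNA quality on the array, the 3' minus the 5' probe set of beta-actin, hexokinase and GAPDH, had higher means at 24 and 27 months than at 6 months. For actin the difference was 0.160 ± 0.0385 log2 (SD, n = 10) at 6 months, 0.195 at 12, 0.171 at 18, 0.180 at 21, 0.240 ± 0.0683 (n = 9) at 24 and 0.326 ± 0.1003 (n = 7) at 27 months. For hexokinase it was -0.274 ± 0.159 at 6 months, -0.133 at 12, -0.000194 at 18, 0.0462 at 21, 0.240 ± 0.207 at 24 and 0.253 ± 0.183 at 27 months. For GAPDH it was 0.0852 ± 0.0430 at 6 months, 0.0888 at 12, 0.103 at 18, 0.0784 at 21, 0.162 ± 0.0361 at 24 and 0.146 ± 0.0459 at 27 months. These values stand beside the gene groups described for every later age. Each difference was also added as a covariate, alternatives chosen after seeing the data.

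Between 6 and 27 months genes listed beforehand as the response to lost nerve supply rose, and most listed genes of energy metabolism fell. Nerve supply itself was not measured. Chrna1, the alpha subunit of the muscle acetylcholine receptor, was 31-fold higher (log2 change 4.95 ± 0.29, n = 7 and 10, adjusted p = 2.23e-20). Cdkn1a, the cell cycle inhibitor p21, was 18.8-fold higher (4.23 ± 0.22, adjusted p = 6.63e-22). Tfrc, the transferrin receptor for iron uptake, was 7.89-fold lower (-2.98 ± 0.17, adjusted p = 1.02e-20). In all, 7751 genes changed, 68.9% of those tested, with 3949 higher and 3802 lower. At least a 2-fold change was found for 289 of the higher and 200 of the lower genes. With the values as deposited the split was 4864 higher and 2980 lower, and with arrays centred on their medians 4335 and 3394.

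The other genes among the 10 largest rises were Emb (4.2 ± 0.26), the embryonic myosin heavy chain Myh3 (4.09 ± 0.34), Klk1 (4.08 ± 0.29), Ankrd1 (4.06 ± 0.31), Sln (3.94 ± 0.25), Gadd45a (3.60 ± 0.23), Krt18 (3.59 ± 0.21) and Prrt4 (3.38 ± 0.20). Sln encodes sarcolipin, an inhibitor of the sarcoplasmic calcium pump. Krt18 had a mean of 4.2 at 6 months, close to the floor of 4.00, so its fold is bounded by that floor. The probe sets of Prrt4 changed by between -0.42 and 3.38. The largest falls after Tfrc were Pfkfb1 (-2.49 ± 0.17), the water channel Aqp4 (-2.23 ± 0.23), Mss51 (-2.18 ± 0.15), Slc41a3 (-2.09 ± 0.17) and Slc16a3 (-2.04 ± 0.18), a lactate transporter. Perm1 (-2.0 ± 0.17), Mylk2 (-1.96 ± 0.12), Asb11 (-1.93 ± 0.12) and Palldl1 (-1.86 ± 0.18) followed. For Aqp4, 1 rat of 27 months lay at 5.65 and the next lowest at 7.31.

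Of 38 gene lists fixed before the data were examined, 23 shifted between 27 and 6 months in limma's camera test with its preset correlation, 12 up and 11 down. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.176, while 10 lists had an unadjusted p under 0.05 and fry passed 34. The accounts of lists below therefore give the number of members that changed. Members can move together, so these counts describe a list and do not test it. They stand against 68.9% of all tested genes that changed in this comparison, 3949 higher and 3802 lower. Counts adjusted over the list alone were the same as those adjusted over all genes, except where another number is given.

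All 14 tested genes of the denervation response rose (median change 2.88, list adjusted p = 8.91e-12, adjusted p = 0.176 with an estimated correlation). The acetylcholine receptor subunit Chrng rose by 1.65 ± 0.17 from a mean of 4.55, near the floor. The transcription factors Runx1 and Myog rose by 3.37 ± 0.18 and 2.75 ± 0.17, and the adhesion molecule Ncam1 by 3.09 ± 0.17, with its probe sets between 0.25 and 3.09. Of the 13 genes of synapse structure, 8 rose (median 0.22, list adjusted p = 0.00562, adjusted p = 0.176 with an estimated correlation). They included Erbb2 (1.32 ± 0.12), the adult receptor subunit Chrne (1.22 ± 0.11) and Lrp4 (0.74 ± 0.07), as well as Lama5 (1.34 ± 0.09), whose probe sets ranged from -0.14 to 1.34. Of 8 developmental sarcomere genes 7 rose, among them Tnnt2 (3.09 ± 0.24), Myl4 (2.45 ± 0.39) and Mybph (1.60 ± 0.23). That list's median was 1.06, with list adjusted p = 0.00578 and adjusted p = 0.176 with an estimated correlation.

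**Figure D1:**
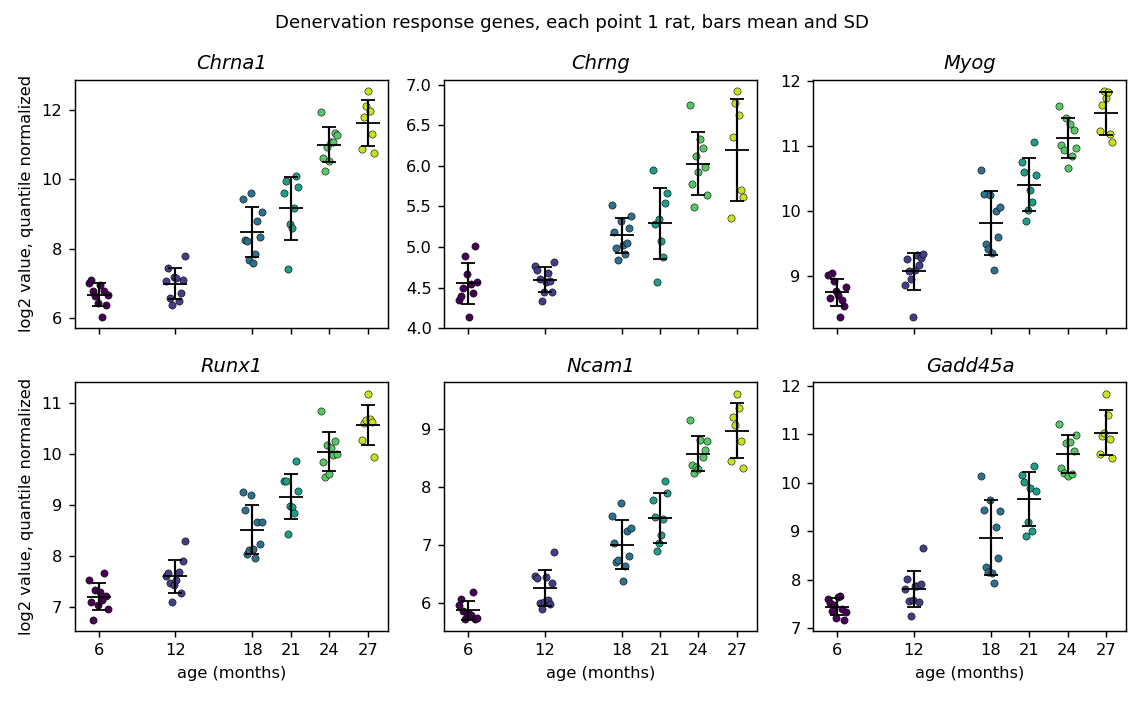
Log2 values after quantile normalization of 6 denervation response genes (Chrna1, Chrng, Myog, Runx1, Ncam1 and Gadd45a) against age in months, with 1 point per rat and bars for mean and SD. Between 6 and 27 months the means differed by 4.95 for Chrna1, 3.60 for Gadd45a, 3.37 for Runx1, 3.09 for Ncam1, 2.75 for Myog and 1.65 for Chrng.

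Most genes of the mitochondrial lists fell. Of the 34 tested subunit genes of complex I, the first enzyme of the respiratory chain, 33 fell (median -0.54, list adjusted p = 2.43e-16, adjusted p = 0.176 with an estimated correlation). Ndufs8 changed by -0.84 ± 0.06, Ndufa5 by -0.62 ± 0.05 and Ndufb4 by -0.44 ± 0.03, while Ndufs4 was at -0.02 ± 0.04. All 12 genes of complexes II and III fell (median -0.48, list adjusted p = 4.38e-07, adjusted p = 0.187 with an estimated correlation), such as Uqcrfs1 (-0.62 ± 0.06) and Sdhc (-0.52 ± 0.05). Of 18 complex IV genes 14 fell, such as Cox10 (-1.0 ± 0.08), and 3 rose, Cox7a1 (2.33 ± 0.23), Cox8a (0.58 ± 0.06) and Cox6a1 (0.25 ± 0.04). The median was -0.37, with list adjusted p = 0.000912 and adjusted p = 0.259 with an estimated correlation. Of 14 complex V genes 13 fell, such as Atp5f1c (-0.59 ± 0.05), and the inhibitor Atp5if1 rose (0.76 ± 0.07). That list had median -0.44, list adjusted p = 6.17e-07 and adjusted p = 0.176 with an estimated correlation.

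The 57 tested genes of the mitochondrial ribosome included 52 that fell, such as Mrpl15 (-0.63 ± 0.04) and Mrpl50 (-0.75 ± 0.05), and 2 that rose, Mrpl17 (0.16 ± 0.03) and Mrpl23 (0.13 ± 0.04). The median was -0.43, with list adjusted p = 6.56e-16 and adjusted p = 0.176 with an estimated correlation. Of 21 genes of mitochondrial biogenesis and dynamics 15 fell, such as Esrra (-0.72 ± 0.07) and Tfb2m (-0.70 ± 0.06), and Nrf1 (0.33 ± 0.08), Polg2 (0.27 ± 0.07) and Gabpa (0.22 ± 0.05) rose. The list showed a median of -0.32, list adjusted p = 0.00171 and adjusted p = 0.176 with an estimated correlation. Ppargc1a, the coactivator PGC-1alpha, fell by 0.87 ± 0.11. All 16 genes of the citric acid cycle fell (median -0.53, list adjusted p = 8.62e-08, adjusted p = 0.208 with an estimated correlation), such as Idh3a (-0.97 ± 0.08). Of 22 genes of fatty acid oxidation 17 fell, such as Hadh (-0.98 ± 0.09) and Cpt2 (-0.91 ± 0.09), and Decr1 rose (0.38 ± 0.07). The members had median -0.39, list adjusted p = 0.000533 and adjusted p = 0.385 with an estimated correlation. All 16 genes of glycolysis and glycogen fell too (median -0.63, list adjusted p = 4.38e-09, adjusted p = 0.176 with an estimated correlation), such as Phka1 (-1.2 ± 0.09) and Pfkm (-1.04 ± 0.08).

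Most cytosolic ribosome and proteasome genes rose, while the other lists of protein turnover went both ways. Of 32 genes of the cytosolic ribosome 31 rose, and 32 adjusted over the list alone (median 0.40, list adjusted p = 1.27e-14, adjusted p = 0.176 with an estimated correlation), with Rpl3 at 1.13 ± 0.07 and Rps9 at 0.70 ± 0.05. Of 30 proteasome subunit genes 23 rose (median 0.24, list adjusted p = 2.97e-06, adjusted p = 0.208 with an estimated correlation), such as Psma2 (0.51 ± 0.05) and Psmd2 (0.42 ± 0.03). The 17 genes of ubiquitin ligases and atrophy went both ways, 8 higher and 6 lower (median 0.05, list adjusted p = 0.615). Fbxo30 (1.49 ± 0.11) and Nedd4 (0.77 ± 0.05) rose and Usp19 fell (-0.52 ± 0.05). Of the best known atrophy ligases, Trim63 rose by 0.35 ± 0.09 (adjusted p = 0.00107) and Fbxo32 was at -0.08 ± 0.16 (adjusted p = 0.685). Autophagy and lysosome genes split into 8 higher and 7 lower of 19 (list adjusted p = 0.389), with Ctsl at 1.24 ± 0.09 and Ctsb at 0.97 ± 0.06. Their median was -0.01 but their mean was 0.14 and the test pointed up, and the median was 0.09 with the values as deposited and 0.04 with each array centred on its median. Of 17 heat shock and chaperone genes 8 rose and 4 fell (median 0.09, list adjusted p = 0.349), with Hspb8 at 1.15 ± 0.07 and Hspb3 at -0.39 ± 0.06.

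All 14 macrophage and myeloid genes rose (median 1.11, list adjusted p = 3.91e-07, adjusted p = 0.208 with an estimated correlation), such as Tyrobp (1.37 ± 0.12), Laptm5 (1.30 ± 0.12) and Lyz2 (1.11 ± 0.11). All 7 complement genes rose (median 1.02, list adjusted p = 0.000672, adjusted p = 0.246 with an estimated correlation), such as C1qc (1.33 ± 0.13) and Serping1 (1.01 ± 0.09). Of 21 interferon response genes 19 rose (median 0.64, list adjusted p = 0.000199, adjusted p = 0.285 with an estimated correlation), such as Psmb8 (1.34 ± 0.15) and B2m (0.97 ± 0.06). Of 14 cytokines and chemokines 11 rose, such as Ccl5 (1.56 ± 0.14), and Il15 (-1.54 ± 0.16) and Ccl4 (-0.33 ± 0.12) fell. That list had median 0.74, list adjusted p = 0.024 and adjusted p = 0.285 with an estimated correlation. Of 8 genes of class II antigen presentation RT1-Da (1.34 ± 0.12), RT1-Db1 (1.16 ± 0.13), Cd74 (1.12 ± 0.11) and RT1-DMa (1.04 ± 0.11) rose and Ciita (-0.54 ± 0.10) fell, with its probe sets between -0.54 and 0.30. Its median was 1.09, with list adjusted p = 0.0441 and adjusted p = 0.326 with an estimated correlation. Of 6 T and B cell genes Cd4 (0.88 ± 0.09), Cd8b (0.52 ± 0.11), Lck (0.33 ± 0.09) and Cd3e (0.19 ± 0.07) rose and Cd2 (-0.40 ± 0.08) fell (median 0.26, list adjusted p = 0.287).

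Endothelial and mural genes had a median of 0.09 (list adjusted p = 0.514), with 6 of 15 higher, 5 adjusted over the list alone, among them Pecam1 (0.40 ± 0.09), and Rgs5 lower (-1.03 ± 0.10). Of 9 fibroblast genes Pi16 (0.64 ± 0.14), Pdgfra (0.49 ± 0.08), Dpt (0.36 ± 0.09), Dcn (0.25 ± 0.05) and Gsn (0.17 ± 0.06) rose and Clec3b (-0.48 ± 0.08) fell (median 0.20, list adjusted p = 0.287). Of 13 adipocyte genes 7 rose, such as Scd (3.0 ± 0.38) and Cidea (1.85 ± 0.14), and Plin4 (-1.14 ± 0.15) and Lipe (-0.49 ± 0.06) fell (median 0.50, list adjusted p = 0.243). Of 9 Schwann cell and nerve genes Cnp (1.91 ± 0.13) and Egr2 (0.90 ± 0.18) rose and Mbp (-0.46 ± 0.20), Prph (-0.26 ± 0.09) and Prx (-0.23 ± 0.09) fell (list adjusted p = 0.663). The probe sets of Mbp lay between -0.46 and 0.54. The list's median was -0.02, its mean 0.22 and the test pointed up, and the median was 0.09 with the values as deposited and 0.04 with each array centred on its median. Under either of these scalings 2 genes rose and 1 fell. Of 9 satellite cell and Notch genes Sdc4 (0.46 ± 0.13), Hes1 (0.37 ± 0.09), Itga7 (0.22 ± 0.07) and Notch1 (0.16 ± 0.06) rose, and Heyl (-0.80 ± 0.09), Notch3 (-0.34 ± 0.08) and Cdh15 (-0.15 ± 0.06) fell (median 0.09, list adjusted p = 0.956). Of 3 red blood cell genes Hbb rose (0.55 ± 0.21), with a list median of 0.19 and list adjusted p = 0.72.

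Among genes of the fibre itself, 8 of 14 fast fibre genes fell, such as Mybpc2 (-0.87 ± 0.07), Myoz1 (-0.61 ± 0.05) and the fast myosin Myh4 (-0.53 ± 0.07), and Myl1 rose (0.10 ± 0.02). The list showed a median of -0.28, list adjusted p = 0.0135 and adjusted p = 0.285 with an estimated correlation. Of 14 slow fibre genes Myl3 (-0.71 ± 0.12), Tpm3 (-0.62 ± 0.18), the slow myosin Myh7 (-0.59 ± 0.20), Atp2a2 (-0.56 ± 0.13) and Myl2 (-0.40 ± 0.15) fell, and Csrp3 (1.28 ± 0.19), Casq2 (0.57 ± 0.16) and Pln (0.21 ± 0.09) rose (median -0.19, list adjusted p = 0.579). The probe sets of Tpm3 changed by between -1.16 and 0.84, and their mean turned its direction to 0.18 (adjusted p = 0.014). Those of Atp2a2 lay between -0.73 and 0.05. Of 14 genes of excitation-contraction coupling 9 fell, such as Kcnj11 (-0.84 ± 0.06) and Cacna1s (-0.65 ± 0.06), and Kcnma1 (0.94 ± 0.09) and Cacnb1 (0.66 ± 0.07) rose. The members had median -0.33, list adjusted p = 0.0208 and adjusted p = 0.315 with an estimated correlation.

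Growth and stress pathways changed in both directions. Of 24 genes of growth factor and myostatin signalling 13 rose, such as Fst (2.08 ± 0.15), Tgfb2 (1.33 ± 0.09) and Igf2 (2.53 ± 0.13), whose probe sets ranged from -0.40 to 2.53. Mstn, myostatin, which restrains muscle growth, fell by 1.45 ± 0.16, as did Irs1 (-0.73 ± 0.14), Inhba (-0.43 ± 0.08) and Acvr2b (-0.24 ± 0.06). The list had median 0.29, list adjusted p = 0.0312 and adjusted p = 0.176 with an estimated correlation. Of 16 genes of p53 targets and cell cycle arrest 11 rose, such as Phlda3 (1.87 ± 0.13) and Mdm2 (0.85 ± 0.07), and Sesn1 fell (-0.88 ± 0.09). That list had median 0.36, list adjusted p = 0.00154 and adjusted p = 0.176 with an estimated correlation, and it shares Cdkn1a and Gadd45a with the denervation list. Of 24 oxidative stress genes 14 rose and 6 fell (median 0.23, list adjusted p = 0.123), with Gpx3 at 1.31 ± 0.10 and Prdx5 at -0.63 ± 0.05. Of 10 cell proliferation genes Mcm6 (0.52 ± 0.09), Top2a (0.48 ± 0.13), Mcm4 (0.31 ± 0.06), Mcm7 (0.23 ± 0.06) and Pcna (0.21 ± 0.04) rose, 6 adjusted over the list alone, and Ccnb1 (-0.28 ± 0.09) and Mcm5 (-0.16 ± 0.07) fell (median 0.21, list adjusted p = 0.243). The probe sets of Top2a lay between -0.58 and 0.48. Of 16 circadian clock genes 7 fell, 6 adjusted over the list alone, such as Nfil3 (-1.06 ± 0.21) and Nr1d1 (-0.82 ± 0.22) (median -0.21, list adjusted p = 0.243). With the values as deposited 4 fell and 1 rose, and with arrays centred on their medians 4 fell. Of 29 extracellular matrix genes 15 rose and 6 fell (median 0.22, list adjusted p = 0.127), with Ccn2 at 1.34 ± 0.18, Bgn at 1.05 ± 0.12 and the collagen gene Col1a1 at -1.10 ± 0.19.

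Some gene calls at 27 months were lost when a measure of RNA quality was added as a covariate. With actin they include Adipoq, from 0.96 ± 0.28 to 0.35 ± 0.36 (adjusted p = 0.43), Myh7, at -0.48 ± 0.26 (adjusted p = 0.124), and Hbb, at 0.33 ± 0.28 (adjusted p = 0.343). The others named above with actin were Lck at 0.13 ± 0.11 (adjusted p = 0.335), Mcm4 at 0.14 ± 0.06 (adjusted p = 0.0616), Pi16 at 0.38 ± 0.18 (adjusted p = 0.0621) and Tpm3 at -0.49 ± 0.23 (adjusted p = 0.0731). With hexokinase they were Hbb at 0.35 ± 0.28 (adjusted p = 0.29), Myh7 at -0.35 ± 0.26 (adjusted p = 0.246), Tpm3 at -0.34 ± 0.22 (adjusted p = 0.193), Atp2a2 at -0.37 ± 0.17 (adjusted p = 0.0601), Lck at 0.25 ± 0.12 (adjusted p = 0.0682) and Sdc4 at 0.32 ± 0.17 (adjusted p = 0.0965), as well as Nr1d1 at -0.55 ± 0.28 (adjusted p = 0.0968), Prph at -0.24 ± 0.12 (adjusted p = 0.0799) and Prx at -0.12 ± 0.12 (adjusted p = 0.412). With GAPDH it was Prx at -0.21 ± 0.10 (adjusted p = 0.0737). Without replicate 98 Myh7 was at -0.31 (adjusted p = 0.0853), and without replicate 99 Hbb was at 0.47 (adjusted p = 0.0609). Prx did not pass under 8 alternatives (adjusted p from 0.0532 to 0.412), among them the values as deposited, at -0.16 (adjusted p = 0.143).

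**Figure D2:**
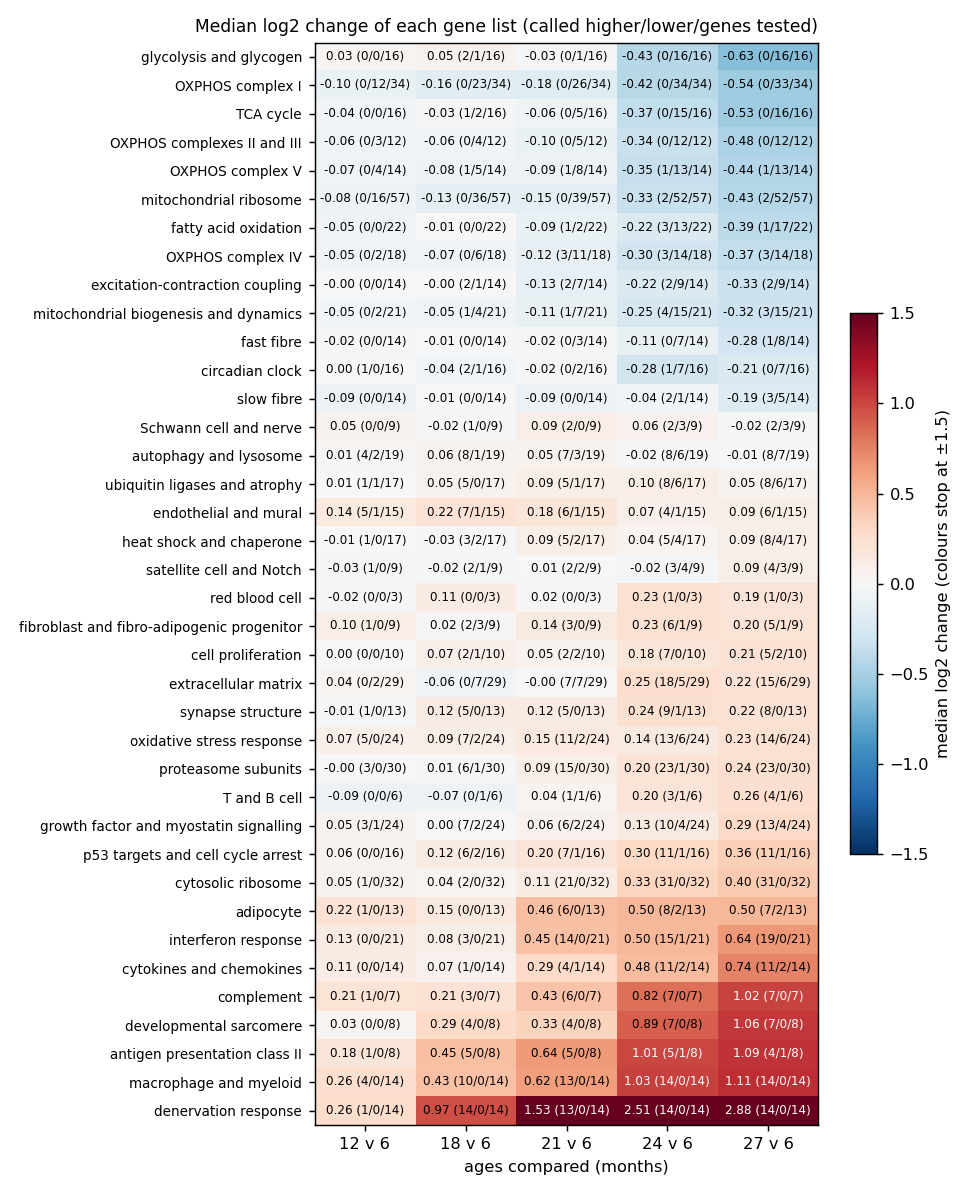
Median log2 change of the tested members of each of 38 gene lists (vertical) for 12, 18, 21, 24 and 27 months against 6 months (horizontal), in colour and figures, with the numbers of genes higher, lower and tested in brackets. The denervation response reached a median of 0.97 at 18 months and 2.88 at 27 months, and complex I one of -0.54 at 27 months.

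At 12 months the muscle differed from that at 6 months by small amounts (n = 10 and 10). The transferrin receptor Tfrc was lower by then (-0.70 ± 0.15), as were Chac1 (-0.88 ± 0.27) and Frat2 (-0.74 ± 0.13), and Stmn2 (0.54 ± 0.10), Prrt4 (0.53 ± 0.18) and Cst7 (0.53 ± 0.18) were the 3 largest rises. In total 1166 genes changed, 566 higher and 600 lower, none of them by 2-fold, and 2842 had an unadjusted p under 0.05. The deposited values split them 731 higher and 318 lower, and arrays centred on their medians 672 and 274. Complex I held 12 of 34 genes that fell, 17 adjusted over the list alone (median -0.10, list adjusted p = 6.73e-11, adjusted p = 0.714 with an estimated correlation). The mitochondrial ribosome held 16 of 57 that fell, 24 adjusted over the list alone (median -0.08, list adjusted p = 4.95e-12, adjusted p = 0.714 with an estimated correlation). Macrophage genes Lyz2 (0.38 ± 0.10), Mrc1 (0.37 ± 0.11), Laptm5 (0.35 ± 0.11) and Csf1r (0.32 ± 0.09) rose, chosen after their values were seen, with 6 of 14 adjusted over the list alone (list adjusted p = 0.000265, adjusted p = 0.714 with an estimated correlation). Chrna1 (0.31 ± 0.26, adjusted p = 0.476) and Cdkn1a (0.51 ± 0.20, adjusted p = 0.0875) did not pass. For Prrt4 and Tfrc 1 rat of 12 months, replicate 43, lay apart from the rest of its age. Prrt4 did not pass under 7 alternatives (adjusted p from 0.0507 to 0.225), among them the mean of its probe sets, at 0.13, and the covariates of actin, at 0.50 ± 0.18 (adjusted p = 0.0772), and hexokinase, at 0.47 ± 0.18 (adjusted p = 0.09). Cst7 did not pass under 4 (adjusted p from 0.053 to 0.0717), with changes of 0.54 ± 0.18 with the actin covariate and 0.51 ± 0.19 with that of hexokinase, nor Chac1 with the actin covariate, at -0.77 ± 0.27 (adjusted p = 0.0556).

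By 18 months the denervation genes had risen (n = 10 and 10). Chrna1 was 3.50-fold higher than at 6 months (1.81 ± 0.26), Cdkn1a 2.95-fold (1.56 ± 0.20) and Sln rose by 1.56 ± 0.23, the 3 largest rises. Nr4a3 (-1.34 ± 0.46), Obp3 (-1.33 ± 0.24) and Cish (-1.30 ± 0.41) were the largest falls. All 14 denervation response genes rose (median 0.97, list adjusted p = 8.27e-15, adjusted p = 0.156 with an estimated correlation), with Runx1 at 1.32 ± 0.17 and Myog at 1.06 ± 0.15. Complex I held 23 of 34 genes that fell, 28 adjusted over the list alone (median -0.16, list adjusted p = 3.99e-12, adjusted p = 0.348 with an estimated correlation). The mitochondrial ribosome held 36 of 57, 42 adjusted over the list alone (median -0.13, list adjusted p = 1.17e-15, adjusted p = 0.317 with an estimated correlation). Macrophage genes rose in 10 of 14 cases, 12 adjusted over the list alone (list adjusted p = 1.01e-05, adjusted p = 0.36 with an estimated correlation), and endothelial and mural genes in 7 of 15, 10 adjusted over the list alone (list adjusted p = 0.00128, adjusted p = 0.348 with an estimated correlation), while Rgs5 fell (-0.56 ± 0.09). Matrix genes included 7 that fell, among them Col1a1 (-0.99 ± 0.17), Col1a2 (-0.90 ± 0.14) and Sparc (-0.72 ± 0.09), with list adjusted p = 0.0546. In total 2883 genes changed, 1418 higher and 1465 lower, with the values as deposited 2135 and 873, and with arrays centred on their medians 1074 and 1544, so the direction of the split depends on the scaling. With only the arrays of both ages Nr4a3 had an adjusted p of 0.0529.

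At 21 months, compared with 6 months, Chrna1 was 5.62-fold higher (2.49 ± 0.28, n = 8 and 10) and Cdkn1a (2.31 ± 0.21) and Gadd45a (2.23 ± 0.22) followed. Nr4a3 (-1.45 ± 0.49), Col1a1 (-1.26 ± 0.18) and Cdh22 (-1.12 ± 0.10) fell most. Of 14 denervation response genes 13 rose, 14 adjusted over the list alone (median 1.53, list adjusted p = 2.15e-16, adjusted p = 0.113 with an estimated correlation). Of 34 complex I genes 26 fell, 27 adjusted over the list alone (median -0.18, list adjusted p = 3.19e-11, adjusted p = 0.359 with an estimated correlation). Of 14 macrophage genes 13 rose, 14 adjusted over the list alone (median 0.62, list adjusted p = 6.39e-08, adjusted p = 0.359 with an estimated correlation). Of 21 interferon response genes 14 rose, 15 adjusted over the list alone, such as B2m (0.56 ± 0.06) (list adjusted p = 7.25e-06, adjusted p = 0.359 with an estimated correlation). Cytosolic ribosome genes rose in 21 of 32 cases, 23 adjusted over the list alone, with Rpl3 at 0.58 ± 0.07 (list adjusted p = 9.25e-07, adjusted p = 0.413 with an estimated correlation). In total 4012 genes changed, 1981 higher and 2031 lower, with the values as deposited 2485 and 1357, and with arrays centred on their medians 2020 and 1641. Ppargc1a was at -0.29 ± 0.10 (adjusted p = 0.0233), at -0.23 (adjusted p = 0.0757) with the values as deposited and at -0.28 ± 0.12 (adjusted p = 0.0744) with the hexokinase covariate.

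At 24 months Chrna1 was 20.1-fold higher than at 6 months (4.33 ± 0.27, n = 9 and 10), Klk1 15.6-fold (3.96 ± 0.27) and Cdkn1a 13.9-fold (3.79 ± 0.20). Tfrc was 4.53-fold lower (-2.18 ± 0.16), followed by Nr4a3 (-1.93 ± 0.47) and Mss51 (-1.82 ± 0.14). All 34 complex I genes fell (median -0.42, list adjusted p = 4.98e-17, adjusted p = 0.2 with an estimated correlation), as did all 16 glycolysis and glycogen genes (median -0.43, list adjusted p = 1.56e-07, adjusted p = 0.201 with an estimated correlation). All 14 denervation response genes rose (median 2.51, list adjusted p = 5.22e-14, adjusted p = 0.2 with an estimated correlation), and so did all 14 macrophage genes (median 1.03, list adjusted p = 1.2e-08, adjusted p = 0.2 with an estimated correlation). Of 29 matrix genes 18 rose, such as Timp1 (1.08 ± 0.18) and Bgn (0.98 ± 0.11), and Col1a1 (-0.88 ± 0.18), Col1a2 (-0.56 ± 0.14), Col5a1 (-0.41 ± 0.09), Col15a1 (-0.40 ± 0.12) and Sparc (-0.36 ± 0.09) fell (median 0.25, list adjusted p = 0.0353, adjusted p = 0.566 with an estimated correlation). In total 7065 genes changed, 3512 higher and 3553 lower, with the values as deposited 4404 and 2682, and with arrays centred on their medians 3499 and 3412. Adipoq was called at 0.72 ± 0.26 but was at 0.43 ± 0.27 (adjusted p = 0.178) with the actin covariate and at 0.60 ± 0.31 (adjusted p = 0.0963) with that of GAPDH.

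The steps between neighbouring ages ask when the changes occurred. Cohort, batch and time since purchase may differ between ages too, and a step cannot tell them apart from age. From 12 to 18 months 85 genes changed, 48 higher and 37 lower (n = 10 and 10). Chrna1 rose 2.81-fold (1.49 ± 0.26), Myh3 by 1.31 ± 0.31 and Sln by 1.2 ± 0.23, and Ecrg4 (-0.88 ± 0.22), Pdgfrl (-0.51 ± 0.10) and Clec11a (-0.49 ± 0.09) fell most. The probe sets of Clec11a changed by between -0.13 and 0.03 from 6 to 27 months. Of 14 denervation response genes 9 rose, 13 adjusted over the list alone, among them Gadd45a (1.06 ± 0.21), Cdkn1a (1.05 ± 0.20), Runx1 (0.92 ± 0.17) and Myog (0.74 ± 0.15). Its median was 0.76 with list adjusted p = 2.81e-25, and this list alone of the 38 also passed in this step with an estimated correlation (adjusted p = 0.0117). The count was 214 with arrays centred on their medians, 31 higher and 183 lower, and 223 with array weights. It was 173 with only the arrays of both ages and 51 with the mean of each gene's probe sets, and the values as deposited gave 56 higher and 17 lower. With the hexokinase covariate the count was 52. Ecrg4 had an adjusted p of 0.058 with only the arrays of both ages. With the hexokinase covariate it was at -0.87 ± 0.23 (adjusted p = 0.0596) and Myh3 at 1.2 ± 0.31 (adjusted p = 0.0635), changes close to those without it.

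From 18 to 21 months 1039 genes changed, 553 higher and 486 lower (n = 8 and 10). Scd, a fatty acid desaturase, rose 2.93-fold (1.55 ± 0.36), Apod by 1.24 ± 0.29 and Pla2g2a by 1.17 ± 0.33, and Acss1 (-0.60 ± 0.13), Wipf3 (-0.51 ± 0.12) and Pnisr (-0.47 ± 0.06) fell most. Of 21 interferon response genes 7 rose, 8 adjusted over the list alone, such as Irf7 (0.56 ± 0.18) and Isg15 (0.51 ± 0.14) (median 0.24, list adjusted p = 6.3e-06, adjusted p = 0.576 with an estimated correlation). Of 14 denervation response genes 6 rose, 9 adjusted over the list alone (median 0.52, list adjusted p = 2.21e-05, adjusted p = 0.576 with an estimated correlation). With only the arrays of both ages Cdkn1a (adjusted p = 0.0553), Gadd45a (adjusted p = 0.0878) and Myog (adjusted p = 0.0588) no longer passed. Arrays centred on their medians gave 713 higher and 201 lower, and the values as deposited 445 and 382.

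From 21 to 24 months 3841 genes changed, 1903 higher and 1938 lower (n = 9 and 8). Tmem158 rose 6.21-fold (2.64 ± 0.17), Myh3 by 2.24 ± 0.34 and Emb by 2.22 ± 0.26, and Pfkfb3 (-1.29 ± 0.27), Slc41a3 (-1.25 ± 0.17) and Lpin1 (-1.24 ± 0.13) fell most. Complex I genes fell in 33 of 34 cases (median -0.24, list adjusted p = 1.75e-17, adjusted p = 0.146 with an estimated correlation), and glycolysis and glycogen genes in 15 of 16, 16 adjusted over the list alone (median -0.39, list adjusted p = 6.65e-15, adjusted p = 0.13 with an estimated correlation). Cytosolic ribosome genes rose in 31 of 32 cases (median 0.20, list adjusted p = 2.29e-18, adjusted p = 0.131 with an estimated correlation). All 14 denervation response genes rose (median 0.86, list adjusted p = 1.31e-10, adjusted p = 0.13 with an estimated correlation). Of 29 matrix genes 13 rose, 15 adjusted over the list alone, such as Postn (1.08 ± 0.22) (median 0.31, list adjusted p = 8.29e-05, adjusted p = 0.356 with an estimated correlation). The values as deposited gave 2230 higher and 1530 lower, and arrays centred on their medians 1598 and 1945. The count of 3841 was 2937 with the actin covariate, 3050 with that of hexokinase and 2499 with that of GAPDH. The highest purchase age given is 20 months, and no purchase age is tied to an animal. Time since purchase may therefore differ between rats of 21 and 24 months, and its part in this step was not tested.

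From 24 to 27 months 855 genes changed, 352 higher and 503 lower (n = 7 and 9), a count that rested on the model and on single rats. Pla2g2a (1.48 ± 0.35), Scd (1.36 ± 0.39) and Krt18 (0.95 ± 0.21) rose most, and Aqp4 (-1.04 ± 0.23), Pdk4 (-0.89 ± 0.27) and the muscle fructose bisphosphatase Fbp2 (-0.88 ± 0.16) fell most. Of 16 glycolysis and glycogen genes 13 fell (median -0.22, list adjusted p = 1.93e-11, adjusted p = 0.255 with an estimated correlation), such as Gpi (-0.47 ± 0.11) and Phka1 (-0.42 ± 0.09). Of 14 fast fibre genes 6 fell, 8 adjusted over the list alone, such as Myh1 (-0.37 ± 0.08) and Myh4 (-0.35 ± 0.07), and 1 rose (list adjusted p = 0.000378, adjusted p = 0.255 with an estimated correlation). Of 14 denervation response genes limma called 0 (lowest adjusted p = 0.0682), while 6 had an unadjusted p under 0.05, and Chrna1 was at 0.62 ± 0.29 (adjusted p = 0.18). Their median was 0.33, with list adjusted p = 0.000378 and adjusted p = 0.445 with an estimated correlation. With only the arrays of both ages 1 gene was called, a rise, with none of the 6 genes named in this paragraph's opening passing (adjusted p from 0.145 to 0.155). The count was 414 with array weights and 11 with the actin covariate, 4 higher and 7 lower, while the hexokinase covariate gave 863 and that of GAPDH 913. Of the 16 glycolysis and glycogen genes limma called 0 with only the arrays of both ages (12 with an unadjusted p under 0.05, median -0.22) and 0 with the actin covariate (12 with an unadjusted p under 0.05, median -0.16), and 11 fell with array weights. Of the 14 fast fibre genes it called 0 with only the arrays of both ages (5 with an unadjusted p under 0.05, median -0.09) and 0 with the actin covariate (8 with an unadjusted p under 0.05, median -0.07), and 5 fell with array weights. Pdk4 did not pass under 6 alternatives (adjusted p from 0.0831 to 0.361) and Scd under 5 (adjusted p from 0.0547 to 0.242), both among them without replicate 98. With the actin covariate Pdk4 was at -0.58 ± 0.28 and Scd at 1.05 ± 0.41. Aqp4 at -0.83 ± 0.24 (adjusted p = 0.115), Krt18 at 0.85 ± 0.23 (adjusted p = 0.0888), Fbp2 at -0.72 ± 0.17 (adjusted p = 0.0505) and Myh4 at -0.24 ± 0.07 (adjusted p = 0.121) did not pass with it either, their changes being smaller but in the same direction. Without replicate 94 it was 1749, without 96 it was 339, without 97 it was 458, without 98 it was 250, without 99 it was 495 and without the highest-numbered rat it was 1304. The values as deposited gave 505 higher and 405 lower, and arrays centred on their medians 826 and 317.

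The change from 18 to 27 months was set against that from 6 to 18 months by testing their difference, the later minus the earlier (n = 7, 10 and 10). A positive difference can be a larger rise, a smaller fall or a turn, and a negative one the reverse. Tmem158 (3.19 ± 0.28), Pla2g2a (2.72 ± 0.56) and Apod (2.54 ± 0.49) had the largest positive differences, and Aqp4 (-2.56 ± 0.37), Pfkfb1 (-2.07 ± 0.28) and Slc16a3 (-1.99 ± 0.29) the largest negative ones. In total 4187 genes differed, 2105 positive and 2082 negative, 2719 and 1391 with arrays centred on their medians, and 1999 and 2056 with the values as deposited. All 16 glycolysis and glycogen genes had a negative difference (median -0.64, against a median change of 0.05 from 6 to 18 months, list adjusted p = 7.91e-16, adjusted p = 0.242 with an estimated correlation), such as Phkg1 (-1.5 ± 0.20) and Gpi (-1.43 ± 0.17). Cytosolic ribosome genes had a positive difference in 31 of 32 cases, 32 adjusted over the list alone (median 0.34, list adjusted p = 1.03e-16, adjusted p = 0.295 with an estimated correlation). Of 29 matrix genes 14 had a positive difference, 17 adjusted over the list alone, such as Lox (1.79 ± 0.35) and Thbs4 (1.70 ± 0.34) (median 0.54, list adjusted p = 7.51e-05, adjusted p = 0.453 with an estimated correlation). Col1a1 is among them (0.88 ± 0.31), though it lay below its 6-month level by 0.99 at 18 months and by 1.10 at 27 months, and its difference was 0.72 ± 0.34 (adjusted p = 0.116) with the actin covariate. Of 15 endothelial and mural genes, a list with 7 rises by 18 months, 6 had a negative difference, 7 adjusted over the list alone, such as Vwf (-0.64 ± 0.17) and Kdr (-0.62 ± 0.18) (median -0.26, list adjusted p = 0.00903, adjusted p = 0.453 with an estimated correlation). Of 14 denervation response genes 6 had a positive difference, 12 adjusted over the list alone (median 0.68, list adjusted p = 0.00248, adjusted p = 0.454 with an estimated correlation). With the actin covariate Chrna1 was at 1.14 ± 0.52 (adjusted p = 0.101), from 1.34 ± 0.47 (adjusted p = 0.0202), and Cdkn1a at 0.87 ± 0.39 (adjusted p = 0.0919), from 1.11 ± 0.35 (adjusted p = 0.011). Both calls ended through a somewhat smaller change with a larger error, and both passed with the hexokinase and GAPDH covariates. Runx1, at 0.74 ± 0.30 (adjusted p = 0.0467), was at 0.59 ± 0.33 (adjusted p = 0.194) with the actin covariate and did not pass under 10 alternatives in all (lowest adjusted p = 0.0505).

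A straight line on age fitted 7947 genes with a slope other than 0, 3967 upward and 3980 downward, and 4927 and 3031 with the values as deposited. Chrna1 rose by 0.24 log2 per month and Cdkn1a by 0.21, over 54 arrays.

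The spread between rats of the same age did not pass the test against 6 months at any later age. The mean distance of a rat from the others of its age was 0.175 ± 0.0187 log2 (SD, n = 10) at 6 months and 0.201 ± 0.0426 (n = 7) at 27 months. The ratio was 1.14 (exact two-sided permutation p = 0.113, adjusted p = 0.188 over 5 ages), and the adjusted p of the other ages lay between 0.188 and 0.934.

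Rats with higher denervation scores than others of their age had lower complex I scores. After each age's mean was subtracted, Pearson's r was -0.561 over 54 rats (two-sided permutation p = 0.00018, adjusted p = 0.00054 over 3 relations) and Spearman's rho -0.572 (permutation p = 9e-05, adjusted p = 0.00027). Without the 2 rats farthest from the median denervation score r was -0.554 (adjusted p = 3e-04). Within single ages r was 0.677 at 6 months (permutation p = 0.0295), -0.663 at 12 months (permutation p = 0.0406), -0.580 at 18 months, -0.604 at 21 months, -0.456 at 24 months and -0.857 at 27 months (exact p = 0.0321). None of the 18 relations within single ages passed after adjustment (lowest adjusted p = 0.183). The sign at 6 months was opposite to that at the 5 other ages, a difference not tested itself. Of 1000 random lists matched to complex I on brightness, 4.2% had an r as low. Denervation and extracellular matrix scores had r = 0.154 (permutation p = 0.3, adjusted p = 0.3) and rho = 0.0890 (permutation p = 0.523, adjusted p = 0.523), and r = 0.201 without the 2 farthest rats. Denervation and ubiquitin ligase scores had r = 0.253 (permutation p = 0.0951, adjusted p = 0.143) and rho = 0.289 (permutation p = 0.0495, adjusted p = 0.0743), and r = 0.242 without the 2 farthest rats. The latter r was 0.367 (adjusted p = 0.0167) with the values as deposited, 0.307 (adjusted p = 0.0466) with arrays centred on their medians and 0.767 (adjusted p = 3e-05) for first principal components of the lists.

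**Figure D3:**
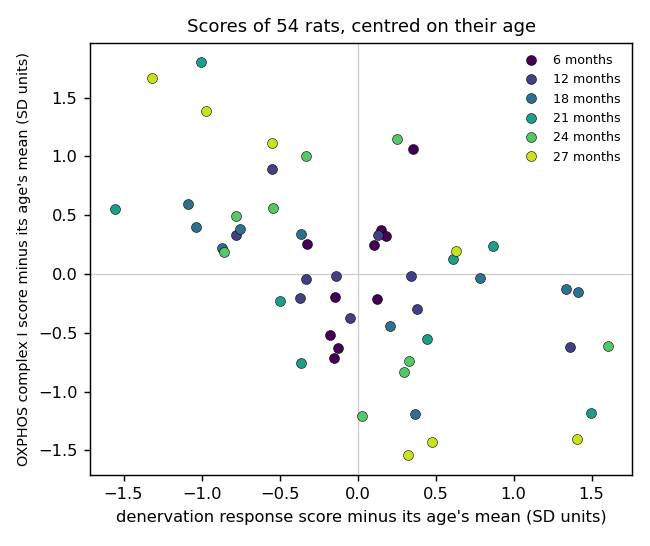
Each of 54 rats by its denervation response score (horizontal) and its complex I score (vertical), both minus the mean of its age, in units of the standard deviation within ages and coloured by age. Pearson's r was -0.561 over all rats, 0.677 at 6 months and -0.857 at 27 months.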

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

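The test of complex I against fast fibre genes and the test of macrophage against endothelial genes were chosen only after the result was seen, as were the fits with the actin, hexokinase and GAPDH covariates and the tests built on them. Predictions first drafted for a wider spread between rats at 27 months were replaced before any test of them, because that difference was not called, by those for the relation within ages, a pattern picked once its r had been seen.

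Of 252 groups of rats, 42 measures at 6 ages, 10 held 1 rat far from the rest by Dixon's ratio, the gap to the nearest other value over the whole range. Chance gives about 1 in 20. At 27 months replicate 94 had the lowest actin difference (0.107, the next 0.330, ratio 0.748) and replicate 98 the lowest Aqp4 value (5.65, the next 7.31, ratio 0.587). At 12 months replicate 43 was highest for Klk1 (ratio 0.67) and Prrt4 (ratio 0.537) and lowest for Tfrc (ratio 0.477), and replicate 27 was lowest for Myog (ratio 0.499). The other ratios were 0.517 for the highest denervation score at 24 months (replicate 72) and 0.598 for the highest Trim63 value there (replicate 80). At 21 months the lowest Myh7 value (replicate 59) had a ratio of 0.645, and at 6 months the highest Slc41a3 value (replicate 6) one of 0.486.

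The change from 18 to 27 months differed from that from 6 to 18 months for 4187 genes, by a test of the difference itself.

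The first pattern weighed is the lower level of mitochondrial lists at 27 than at 6 months. Of 10000 random lists matched to complex I on brightness, 0.01% had a median as low as its -0.54, with the central 95% from -0.30 to 0.18, which argues against a fall of all genes of like brightness. The mean complex I change of -0.55 ± 0.0415 was -0.51 ± 0.0546 with the actin covariate, -0.49 ± 0.0532 with that of hexokinase and -0.55 ± 0.0460 with that of GAPDH, which argues against RNA quality, as these 3 measures track it, as the whole cause. The complex I change lay further down than that of fast fibre genes in the same arrays, the difference being -0.27 log2. All 7 rats of 27 months lay below all 10 of 6 months (exact two-sided p = 5.14e-05, the smallest that 19448 regroupings can give). This argues against a lower share of fibre RNA as the whole cause only if fast fibre transcripts track that share. Glycolysis and glycogen genes had a median change of -0.63, below that of complex I. Whether either list tracks the share of fibre RNA was not tested, so that share stays open as a cause. These tests covered complex I alone, and the other mitochondrial lists were not tested in these ways. A fall of mitochondrial transcripts with age within fibres may underlie the pattern and stays a hypothesis, as do differences between cohorts of rats, since no batch or litter is given.

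The second is the higher level of macrophage genes at 27 months. Their mean rose by 1.15 and that of endothelial and mural genes by 0.06, a difference of 1.09 (exact two-sided permutation p = 5.14e-05, the smallest possible, all 7 rats above all 10). A lower share of fibre RNA would raise markers of every other cell type alike. This argues against it as the whole cause only if endothelial and mural RNA did not itself fall, which would hide such a rise. Between 27 and 6 months 6 of these 15 genes were higher and 1 was lower, Rgs5 (-1.03 ± 0.10). Some, such as Vwf and Kdr, had a negative difference of the late against the early change. Whether this list tracks that share was not tested. The macrophage change of 1.15 ± 0.113 was 0.90 ± 0.141 with the actin covariate, 0.92 ± 0.141 with that of hexokinase and 1.12 ± 0.125 with that of GAPDH, which argues against RNA quality, as these 3 measures track it, as the whole cause. More macrophages, or more of these transcripts in each, may account for it, and these data do not part these.

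The third is the lower complex I score within ages in rats with a higher denervation score. After regression on the actin difference r was -0.550 (permutation p = 0.00012), on that of hexokinase -0.528 (permutation p = 0.00022) and on that of GAPDH -0.562 (permutation p = 0.00018), which argues against RNA quality, as these 3 measures track it, as the whole cause. Among 1000 random lists matched on brightness 4.2% had an r as low as -0.561, with a median of -0.186 and a range from -0.728 to 0.752, so a shift shared by many genes of an array may account for it. A link between nerve supply and mitochondrial transcripts within a rat stays open and untested.

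Other splits of the same arrays into groups of the same sizes, 100 for each result with the real one included, were drawn to ask whether chance can be excluded. The real split alone gave as many genes, 1 of 100, in 9 results. These were 12 against 6 months (1166 genes, highest other 89), 18 against 6 (2883, 73), 21 against 6 (4012, 1641), 24 against 6 (7065, 4783), 27 against 6 (7751, 4689), 18 against 12 (85, 9), 21 against 18 (1039, 107), 24 against 21 (3841, 1048) and the slope on age (7947, 14). For 27 against 24 months 3 of 100 splits gave at least 855 genes, the highest other 1628, and for the late against the early change 2 of 100 gave at least 4187, the highest other 5640. The share was under 0.05 for each of these 11 counts, without adjustment over the results. Chance is not excluded for the 27 against 24 month count, which also rested on the model and on single rats. Why some splits gave more calls than the real one for 27 against 24 months was not tested. For the late against the early change the splits shuffled rats of 6, 18 and 27 months together. They ask whether these ages differ at all, and a split that mixes ages can carry the difference between 27 and 6 months into this contrast. The share of 2 of 100 is thus no test of the late against the early change. Splits of this kind cannot part age from cohort or batch. For the 23 lists, 8 of 100 splits gave as many, the highest other 25 and the median 16, so chance cannot be excluded for that count.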

How the results depend on the processing

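The fits with the actin, hexokinase and GAPDH covariates were chosen only after the result was seen; the other alternatives were set beforehand. Of 5508 values of genes from the fixed rule under all alternatives, 5386 kept their side of the threshold, 97 no longer passed and 24 newly passed. Only 1 was counted as reversed, Tpm3 between 27 and 6 months, 0.18 with the mean of its 12 probe sets. Direction was compared only for values called in either setting. Testing every probe set, 20507 features, raised the counts by testing more: 4518 at 18 against 6 months, 6799 at 21, 12308 at 24, 13684 at 27, 132 at 18 against 12, 2098 at 21 against 18, 6071 at 24 against 21, 6779 for late against early and 14082 for the slope. The 18 against 12 month count of 85 was 214 with arrays centred on their medians, 223 with array weights, 51 with the mean of probe sets, 52 with the hexokinase covariate and 173 with only the arrays of both ages. The 27 against 24 month count of 855 was 414 with array weights, 1 with only the arrays of both ages, 11 with the actin covariate and from 250 to 1749 without 1 rat of 27 months. The 24 against 21 month count of 3841 was 2499 with the GAPDH covariate. Array weights were lowest at 27 months, 0.689. With an estimated correlation 0 lists passed, from 23. The ubiquitin ligase relation had r = 0.367, 0.307 and 0.767 with deposited values, centred arrays and principal components. The cause was not tested where none is given. The remaining counts stayed within 1.5 times: without 1 rat of 27 months, 27 against 6 months gave 7474 to 7829, late against early 3926 to 4534 and the lists 21 to 23, and 27 against 6 months gave 5804, 6304 and 7327 with the actin, hexokinase and GAPDH covariates. The difference in spread, never called, was 0.0123 to 0.0336 log2 without 1 rat. Without the 27-month group the slope count was 6744. The pseudocount alternatives were not run, since the values already were logarithms. No paired analysis was possible because replicate numbers are not shared between ages. The floor of 4.00 limits folds of dim genes.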

Other observations

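Some single genes outside the fixed rule were chosen after their values between 27 and 6 months were seen, and were not recomputed under the alternatives. Agreement between probe sets was looked at only for those that stand in a list. No list or enrichment test covers them as a group, and 68.9% of tested genes changed in this comparison. The iron exporter Slc40a1 was at 1.09 ± 0.10, Hjv, hemojuvelin, at -1.09 ± 0.08 and Alas1, of haem synthesis, at -0.89 ± 0.09. Bola3, of iron-sulfur cluster assembly, was at -0.84 ± 0.06 and the mitochondrial iron carrier Slc25a37 at 0.33 ± 0.08. The ribosomal protein gene Rpl3 rose by 1.13 ± 0.07 while its muscle paralog Rpl3l was at -0.57 ± 0.05. Sat1 was at 1.74 ± 0.12, Odc1 at 0.60 ± 0.08 and Amd1 at -0.50 ± 0.06. Vegfa was at -1.33 ± 0.09, while S100a4 (2.54 ± 0.17), Fgf7 (1.53 ± 0.11), Rb1 (0.88 ± 0.06) and the metallothionein Mt2A (2.58 ± 0.27) rose.

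Rats of 27 months may differ from each other along the direction of ageing more than rats of 6 months do. The prediction was written before the test but after values of the single arrays had been seen. Along the axis that parts 24 from 12 months, set from other rats, the mean absolute deviation from the age's mean was 8.30 ± 3.54 (SD, n = 7) at 27 months and 2.55 ± 1.66 (n = 10) at 6 months (exact two-sided permutation p = 0.000206). Leaving out 1 rat of 27 months at a time gave p from 0.00025 to 0.00425. The axis held 16.9% of the spread between rats at 27 months, 13.8% at 21 months, 4.71% at 18 months and 2.57% at 6 months. The spread over all genes did not differ by the test in the report, so the hypothesis covers this axis alone. The actin difference also varied more between rats at 27 months (SD 0.1003 log2) than at 6 months (0.0385). For hexokinase the SDs were 0.183 at 27 months and 0.159 at 6 months, and for GAPDH 0.0459 and 0.0430. The test along the axis used no measure of RNA quality as a covariate, so RNA quality stays open as a cause.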
